A study of Homo sapiens with 8 samples.

How the data were processed

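The series measured how recombinant human and macaque ZNF626, each with an N-terminal HALO tag, bound a synthetic DNA library (Spec-seq). ZNF626 is a zinc finger protein. Per the labels' protocols, bound and unbound DNA were separated on a native gel by electrophoretic mobility shift, cut out, purified, amplified for at least 12 cycles and sequenced. There were 2 binding reactions per protein and 2 fractions per reaction, so 4 reactions and 8 libraries. The labels do not say whether the 2 reactions of a protein used separate protein preparations, so the p-values measure only the spread between these reactions, which may be technical.

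Each of the 4 deposited tables holds 1 reaction. The authors deposited read counts of the bound and the unbound fraction for each sequence, per the file headers. They also deposited the ratio of bound to unbound reads and an energy on the natural log scale, per the file headers. The recomputed natural log of unbound over bound counts, minus that of the median control ratio, matched the authors' deposited energy within 7.58e-06. No row was blank or held a count of 0. The submitters' processing notes name the genome build hg38, without its role. The read filter, the counting tool and its version are not given in the sources used here. Every table lists the same 1210 sequences of 54 bp, of which 1 is the reference, 1134 are variants of it, 64 are non-specific controls and 11 carry names that begin with HERVK9. The variants are all 63 changes of each of 18 consecutive triplets, with 162 variants of 1, 486 of 2 and 486 of 3 substitutions. The variant names used here were built by counting positions from 942 at the 5' end of the printed strand to 995. The deposited variant labels give only the number of the triplet, and the order of the triplets matched for all variants. The numbering matched the base changes in the deposited names of the HERVK9 sequences. The labels' protocol speaks of 20 degenerate oligos and the design text of 18, and the stated site at 967 to 995 spans 29 bp although its length is given as 30 bp.

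Library totals ran from 1930354 to 6586539 reads. The lowest count of any sequence in any library was 117, and the counting error of a median sequence's energy was 0.0307 to 0.039 kT per reaction. Reads carry no molecular identifiers, so this covers counting error only. The filter of a mean count of at least 10, and the stricter one of 50, removed no sequence.

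Energies are the natural log of unbound over bound reads (pseudocount 0.5) relative to the reference in the same reaction, in kT, where a lower energy means tighter binding and a difference of E stands for a fold of e to the E. The same energies were computed relative to the mean of the 504 variants of the 8 flank triplets (C942 to A965) and of the 64 controls. Counts were tested with edgeR 4.0.16 (quasi-likelihood F test) under R 4.3.3, with the binding reaction as a block, a bound-fraction effect per protein and their difference, on 1134 variants and the 75 other sequences. Library scales were set on the controls for the comparison with controls and on the reference for the comparisons with the reference and between proteins. The reference itself was not tested. Profiles by position (mean of the 3 single substitutions) and by triplet (mean of 63 variants) were tested with limma 3.58.1. Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. For limma on the reference zero the estimated spread was pooled over all positions, and the error of the reference is shared by all of them. Its p-values there thus rest on more degrees of freedom than the 4 reactions give, and very small ones should not be read as strength of replication. The edgeR fit on the control scale likewise pooled the spread over sequences, with infinite prior degrees of freedom. The block came from the labels, which give the bound and the unbound library of a reaction the same table. The deviations of the bound and unbound libraries of the same number correlated at 0.00232 in human and -0.309 in macaque over sequences. Replicate libraries differed by more than sampling noise in all 4 groups, with chi-square values per degree of freedom from 4.41 to 26.3.

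Sequences and positions were named by a rule set before the data were examined. For each protein it took up to 10 positions by size of the mean energy, up to 5 variants bound most strongly and 5 most weakly, and up to 5 triplets, past the adjusted threshold and with the same sign in both reactions. For the difference it took up to 10 positions, 5 variants in each direction and 5 triplets where the reactions of the proteins did not overlap. The lists of triplets, substitution numbers, substituted bases, transitions, transversions and CpG changes were also fixed before the data were examined. Alternatives fixed in advance were other scales (TMM, DESeq2 1.42.0, flank variants, controls), no filter and a stricter one, no replicate block, each protein alone, each reaction left out, another pseudocount, medians, an additive regression and other site borders. The 11 HERVK9 sequences, the single substitutions taken one by one, a crossed block the values without the triplet A978 to A980 and the difference of the profiles on the control zero were added after the data had been seen.

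The edgeR and limma steps were tested on simulated counts drawn from the real means and library sizes. The edgeR simulation changed 200 sequences among 1134 variants. Apart from the set changes, all simulated libraries shared the same composition, with independent noise per sequence. Systematic differences between replicates, as in the real counts, were left out, so the rates below need not hold for the real data. For human against the reference, edgeR recovered 14% of 1.25-fold, 68% of 1.5-fold and 100% of 2-fold changes and called 0.54% of unchanged sequences. For the difference between proteins on that scale it recovered 15.4% of 1.5-fold, 84% of 2-fold and 100% of 4-fold changes. Each scale was simulated with the dispersion of its own fit, 0.0109 for the reference and 0.0307 for the controls. For human against the controls edgeR recovered 28% of 1.5-fold, 74% of 2-fold and 100% of 4-fold changes. In the 54-position profile on the reference zero, limma recovered 100% of human shifts of 0.25 kT, and 0% of 0.25 kT and 100% of 0.5 kT differences between proteins. Each of these shares rests on 5 shifted positions. Summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.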

Results

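Binding energies of human and macaque ZNF626 were measured by Spec-seq, in which a library of DNA sequences is incubated with a protein and the bound and unbound fractions are sequenced. The human ZNF626 gene lies on chromosome 19 at 20619939 to 20661571 (GRCh38.p14). The reference, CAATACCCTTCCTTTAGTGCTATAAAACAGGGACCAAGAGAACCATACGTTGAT, covers positions 942 to 995 in the study's own numbering, counted from its 5' end, and positions are named by the reference base and this number. Its place in the genome was not analysed here. Each protein had 2 reactions with a bound and an unbound library each. The human libraries held 2362585 and 1930354 bound and 3717928 and 3677772 unbound reads, and the macaque libraries 2023945 and 2771595 bound and 5934901 and 6586539 unbound reads. Total bound over unbound was 0.636 and 0.525 in the human reactions and 0.341 and 0.421 in the macaque reactions. Values below are means ± SD over the 2 reactions of a protein (n = 2).

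The first comparison asked which sequences each protein bound apart from the non-specific controls, which differ from the reference at 24 to 27 positions. The controls vary among themselves at only 3 consecutive positions and otherwise share the same sequence. Values and counts relative to the controls thus rest on this shared sequence. Whether either protein binds it specifically was not tested. Human ZNF626 bound the reference more tightly than the controls by 1.73 ± 0.21 kT, a 5.62-fold difference. In macaque the same difference was -0.011 ± 0.167 kT, with one reaction above and one below 0. The exact permutation test of human against macaque gave p = 0.333 (two-sided, n = 2 and 2), which is the smallest p this design allows. With the flank variants in place of the reference, the controls lay 2.19 kT higher in human and 0.181 kT higher in macaque.

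Relative to the controls, human ZNF626 bound 954 of 1134 variants more and 0 less (edgeR), with 0 less also at an unadjusted p under 0.05. DESeq2 with its own size factors, which do not refer to the controls, gave 586 more and 513 less. Macaque ZNF626 bound 97 variants more and 182 less. Of the 97, 41 were changes of triplet A978 to A980, 19 of triplet A966 to A968, 17 of triplet G990 to T992 and 14 of the flank, all 14 in triplet A963 to A965. All 504 flank variants were bound more by human. Of the 567 site variants, 387 were bound more and 180 were not past the test. Adjusted over the list alone, human bound 504 flank and 365 site variants more, and macaque 7 flank, 20 straddling and 74 site variants. The 97 and the 954 shared 86 variants, where independent lists would share 81.6. On this scale, the macaque protein bound 14 variants more and 1070 less than the human protein.

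The macaque counts below the controls depended on which libraries were fitted together, human ones included. They were 0 without human replicate 1, 0 without human replicate 2, 390 without macaque replicate 1 and 58 without macaque replicate 2, and 0 with the macaque libraries alone. The macaque count above the controls was 53 without macaque replicate 1, and the no replicate block fit gave 117 more and 287 less. On scales that do not refer to the controls, TMM gave 591 more and 513 less in human and 199 more and 278 less in macaque, and the flank scale gave 76 more and 561 less in human.

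The second comparison asked how each base change altered binding relative to the reference. In human, the mean over the 3 substitutions at a position was raised from A968 to G972, at C976 and A977, and from A982 to T991 except A986, by 0.430 to 1.33 kT, and at A994, T995, A980 and G993 by 0.610, 0.332, 0.268 and 0.223 kT. At 4 of these positions 1 change had an energy below the reference, A968G at -0.438 ± 0.084, G971A at -0.263 ± 0.002, A980T at -0.347 ± 0.071 and G993T at -1.03 ± 0.12 kT. Position A970 had the highest mean, 1.33 ± 0.13 kT (adjusted p = 8.67e-32, limma, and 1.50e-03 with the zero on the flank variants). It was followed by C976 at 1.21 ± 0.15 kT, C989 at 1.18 ± 0.24 kT, T991 at 1.17 ± 0.18 kT, A977 at 1.16 ± 0.13 kT and A988 at 1.12 ± 0.15 kT. Positions A982, G972 and G990 stood at 1.07 ± 0.15, 1.05 ± 0.10 and 0.988 ± 0.098 kT. Substitutions at G979 tightened binding by mean energy, at -0.978 ± 0.240 kT.

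Outside the stated site, from C942 to A966, all 25 positions had a lower energy than the reference in human, between -0.627 and -0.294 kT. The flank variants as a whole lay at -0.462 ± 0.080 kT in human and -0.193 ± 0.015 kT in macaque relative to the reference, so counts of lower energies depend on the zero. On the reference zero, 20 positions were raised and 33 lowered in human, and with the zero on the flank variants 24 were raised and 4 lowered. On the flank zero, 26 of the 28 called human positions lay in the stated site of 29 positions, with 23 raised there and A978, G979 and A986 lowered. The other called positions were T964 at 0.168 ± 0.055 kT and A965 at -0.165 ± 0.047 kT.

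In macaque the largest mean effect was a tightening at position A980, -1.85 ± 0.05 kT (adjusted p = 3.60e-44, limma, and 5.36e-04 on the flank zero). Position A986 followed at -0.765 ± 0.061 kT, A978 at -0.661 ± 0.027 kT, C975 at -0.634 ± 0.029 kT, A965 at -0.602 ± 0.048 kT and A966 at -0.442 ± 0.036 kT. Binding weakened most at A970, by 0.566 ± 0.149 kT, then A977, C976 and G972 with 0.532 ± 0.173, 0.490 ± 0.216 and 0.455 ± 0.197 kT. On the reference zero, 14 positions were raised and 27 lowered, and on the flank zero 16 raised and 7 lowered. All 16 raised positions lay in the stated site, and A965 and A966 were lowered outside it. Without macaque replicate 2, 4 positions were raised and 9 lowered on the reference zero, and without macaque replicate 1, 8 were lowered. The additive regression gave 16 lowered positions, and there the means at A978 (-0.010 kT) and C975 (-0.078 kT) were no longer past the test, with adjusted p of 0.886 and 0.095 (limma).

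**Figure D1:**
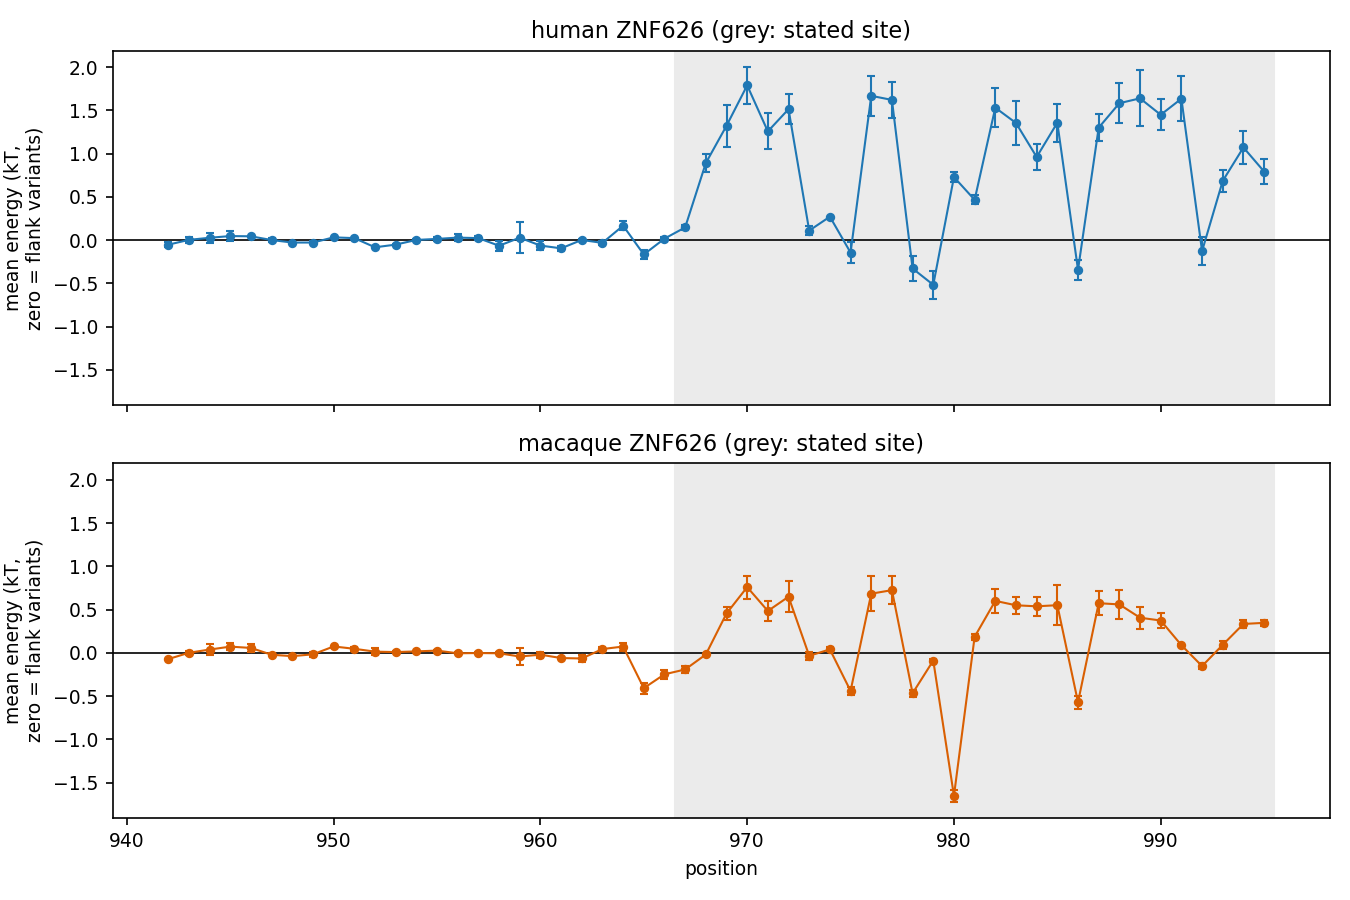
Mean energy of the 3 single substitutions at each position relative to the mean of the flank variants (y axis, kT) against position (x axis), for human (top) and macaque ZNF626 (bottom), with points at the mean and bars at ± SD of 2 reactions, and the stated site in grey. Human means reached 1.79 kT at position A970, and the macaque mean at position A980 was -1.65 kT.

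Among single variants, human ZNF626 bound A978T with G979A most tightly, at -2.03 ± 0.52 kT, 7.63-fold tighter than the reference (edgeR adjusted p = 2.57e-05). A978C with G979A, A978C with G979C and A980T, A978C with G979T, and A978T with G979A and A980T followed at -1.89 ± 0.43, -1.79 ± 0.49, -1.75 ± 0.51 and -1.59 ± 0.43 kT. The weakest were C969T with A970C and G971C, and A970C with G971C, both at 1.55 kT with SD of 0.22 and 0.20. A970T with G971C, T987C with A988G and C989G, and A970G with G971T lay at 1.509 ± 0.283, 1.509 ± 0.237 and 1.505 ± 0.202 kT. These 5 lay 0.178 to 0.221 kT below the mean control (range of means from -0.221 to -0.178 kT). None of them was called against the controls (adjusted p from 0.310 to 0.414, edgeR on the control scale).

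The macaque protein bound G979A with A980T most tightly, at -5.14 ± 0.02 kT or 171-fold (edgeR adjusted p = 6.31e-08). Next came A978C with G979A and A980T at -5.00 ± 0.04 kT, A978T with G979A and A980T at -4.91 ± 0.01 kT, G979C with A980T at -4.44 ± 0.05 kT and G979T with A980T at -3.83 ± 0.09 kT. All 5 carry A980T, which alone gave -3.83 ± 0.09 kT, 45.9-fold. The weakest macaque variants were C969A with A970C and G971C at 0.702 ± 0.240 kT, A977C at 0.690 ± 0.203 kT, C969G with A970G and G971C at 0.679 ± 0.194 kT, A970C with G971C at 0.672 ± 0.236 kT and C976G with A977C at 0.669 ± 0.175 kT. In the fit of the macaque libraries alone, the first 4 of these lost the call, with adjusted p from 0.0531 to 0.058 (edgeR). Relative to the controls, the 5 weakest macaque variants lay at 0.680 to 0.714 kT, with SD of 0.341 to 0.407.

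Against the reference, edgeR called 586 variants bound more and 515 less in human, with 33 not past the test. In macaque it called 249 more, 322 less and 563 not past the test. The share of calls that were higher moved with the scale. On the flank scale human gave 76 more and 561 less and macaque 119 more and 349 less, and on the control scale human gave 954 and 0 and macaque 97 and 182. DESeq2 gave 141 more and 423 less in macaque, and the fit with no replicate block gave 393 and 260. Without macaque replicate 2 the macaque counts were 105 more and 2 less, without human replicate 1 they were 145 and 9, without human replicate 2 they were 143 and 6, and without macaque replicate 1 they were 129 and 300. With the macaque libraries alone they were 143 and 7.

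The fixed lists divided by region. Of the 504 flank variants, 503 were bound more by human and 115 by macaque on the reference scale, and 29 and 22 on the flank scale. Adjusted over the list alone, these were 503, 28, 0 and 5. Of the 567 variants of the 9 site triplets, human bound 68 more and 481 less, and macaque 100 more and 320 less (68, 480, 105 and 337 adjusted over the list alone). The straddling triplet A966 to A968 had 15 of 63 more and 34 less in human and 34 more and 2 less in macaque (15, 33, 34 and 2 adjusted over the list alone). All 64 controls were bound less than the reference by human, and 2 were bound more by macaque, or 0 adjusted over the list alone. As the controls share most of their sequence, they are not 64 independent cases.

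Within the site, the median energy rose with the number of substitutions in human, from 0.772 ± 0.100 kT for 81 single variants to 1.16 ± 0.18 kT for 243 double and 1.26 ± 0.18 kT for 243 triple variants. The macaque medians were 0.194 ± 0.095, 0.360 ± 0.212 and 0.420 ± 0.240 kT. In the flank the human medians were -0.463 ± 0.074, -0.445 ± 0.071 and -0.452 ± 0.077 kT. Single site substitutions to A, C, G and T had human medians of 0.819 ± 0.088, 0.848 ± 0.069, 0.719 ± 0.107 and 0.782 ± 0.116 kT, with 13 of 17, 17 of 21, 14 of 20 and 14 of 23 bound less than the reference. Macaque bound 7 of 17, 10 of 21, 8 of 20 and 9 of 23 less. Transitions and transversions differed by less than the SD in human, at 0.791 ± 0.128 and 0.734 ± 0.086 kT, with 19 of 27 and 39 of 54 bound less. Macaque bound 8 of 27 and 26 of 54 of them less. Adjusted over the list alone, the 4 counts were 18, 39, 8 and 27, and those by substituted base stayed at the values given. The 96 variants that change C989 or G990 lose the CpG. Human bound 94 of them less (median 1.36 ± 0.22 kT) and macaque 55, while macaque bound 22 more. Of the 63 variants each of triplets T987 to C989 and G990 to T992, human bound 63 and 59 less and macaque 53 and 16. CpG loss was thus not separated from a change of these bases. Variants that gained a CpG in the site were bound less in 100 of 117 cases by human and in 65 by macaque. Of all 567 site variants, human bound 481 and macaque 320 less. Adjusted over the list alone, the numbers bound less were 94 and 60 for CpG loss and 100 and 66 for CpG gain.

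By triplet, human energies on the reference zero were highest at T987 to C989 with 1.31 ± 0.21 kT, C969 to G971 with 1.285 ± 0.183 kT, G981 to A983 with 1.19 ± 0.17 kT, G990 to T992 with 1.11 ± 0.16 kT and C975 to A977 with 1.065 ± 0.122 kT. All 18 human triplets were called, 9 raised and 9 lowered (limma). The macaque profile was led by triplet A978 to A980 at -1.525 ± 0.065 kT (adjusted p = 1.59e-18, limma, and 1.79e-03 on the flank zero). Triplets C969 to G971, G981 to A983, T987 to C989 and C975 to A977 lay at 0.501 ± 0.212, 0.472 ± 0.189, 0.438 ± 0.196 and 0.380 ± 0.207 kT. Of the macaque triplets 6 were raised and 5 lowered. On the flank zero human had 9 raised and 0 lowered triplets and macaque 6 and 2. Without macaque replicate 2 the macaque counts were 0 and 1, and without each human replicate they were 0 and 10.

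The third comparison asked where the proteins differed in binding relative to the reference. The macaque protein bound variants that carry A980T more tightly. The energy of G979A with A980T was -5.14 ± 0.02 kT in macaque and -0.628 ± 0.180 kT in human, a 91.3-fold difference (adjusted p = 4.65e-07, edgeR) that was 16.1-fold relative to the controls. For G979T with A980T, G979C with A980T, A978C with G979A and A980T, and A980T alone, binding by macaque was tighter by 57.2-fold, 38.7-fold, 33.8-fold and 32.4-fold relative to the reference, and by 10.1-fold, 6.81-fold, 5.94-fold and 5.70-fold relative to the controls. Relative to the reference, human bound G979T more tightly than macaque, at -1.15 ± 0.32 against -0.195 ± 0.037 kT (2.59-fold, adjusted p = 0.00289, edgeR). The other variants named by the rule as bound more tightly by human were A978C with G979T, A978T with G979T, A978C with G979C and G993T with T995C, by 2.437-fold, 2.435-fold, 2.33-fold and 2.20-fold. With the controls as zero, G979T and these 4 were bound more tightly by human by 14.7-fold, 13.9-fold, 13.8-fold, 13.2-fold and 12.5-fold. On the flank scale the call for A978C with G979T was lost (adjusted p = 0.109, edgeR).

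**Figure D2:**
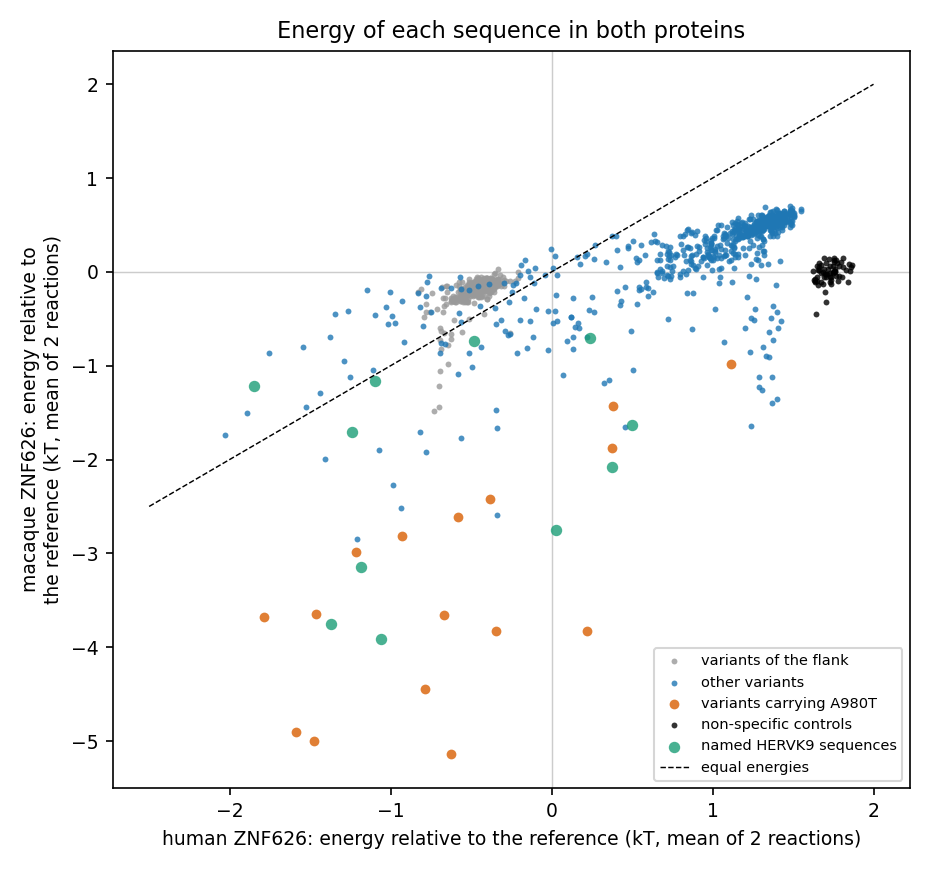
Energy relative to the reference (kT, mean of 2 reactions) of each sequence with human (x axis) and macaque ZNF626 (y axis), with points coloured by class and a dashed line at equal energies. The variants carrying A980T lie below the line, down to -5.14 kT for macaque, and the controls lie near 1.73 kT for human and -0.011 kT for macaque.

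By position the difference of the means (macaque minus human) was -2.115 kT at A980 (adjusted p = 4.62e-36, limma, and 5.02e-04 on the flank zero). There A980T, A980C and A980G stood at -0.347 ± 0.071, 0.455 ± 0.002 and 0.696 ± 0.016 kT in human and at -3.83 ± 0.09, -1.65 ± 0.12 and -0.062 ± 0.045 kT in macaque, the last with adjusted p = 0.453 (limma on single substitutions, chosen after seeing the data). At T991 the human mean was 1.17 ± 0.18 kT and the macaque mean -0.105 ± 0.023 kT. Positions C989, G990, A970, A988, C976, A982 and A968 also had lower energies in macaque, by differences between -0.965 and -0.642 kT, and position G979 had a higher one, by 0.695 kT. The additive regression gave -0.005 kT at G979 (adjusted p = 0.937, limma). By triplet the differences were -1.315 kT at G990 to T992, -1.12 kT at A978 to A980, -0.870 kT at T987 to C989, -0.784 kT at C969 to G971 and -0.716 kT at G981 to A983. The direction of these differences depends on the zero. With the zero on the controls, an alternative chosen after seeing the data, the difference was -0.377 kT at A980 (adjusted p = 0.124, limma), 0.460 kT at T991 (adjusted p = 0.0628, limma) and 0.773 to 1.10 kT at the 7 other positions that were lower in macaque, and the 5 triplets lay at 0.423 to 1.02 kT.

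In counts, the macaque protein bound 554 variants more and 288 less than human relative to the reference (edgeR). Of the 554, 497 were site variants and 52 belonged to the straddling triplet, and of the 288, 262 were flank variants. On the flank scale the counts were 579 and 15, on the control scale 14 and 1070, with TMM 530 and 514, with DESeq2 532 and 523, and with no replicate block 548 and 459. Without human replicate 2 they were 164 and 8, without macaque replicate 1 they were 423 and 21, and without macaque replicate 2 they were 527 and 21. For positions, limma called 22 raised and 18 lowered in macaque against human on the reference zero, and 1 and 26 on the flank zero. The raised positions fell to 2 without macaque replicate 1 and to 1 without macaque replicate 2. For triplets it called 7 raised and 10 lowered, and 0 and 10 on the flank zero. On the control zero, limma called 52 raised and 0 lowered positions and 17 raised and 0 lowered triplets, with 0 lowered also at an unadjusted p under 0.05, while edgeR called 14 variants bound more by macaque on that scale. With a replicate block across proteins, on the reference zero, the positions were 25 and 20 and the triplets 8 and 10. Without human replicate 2 there were 3 raised and 4 lowered triplets, without human replicate 1 there were 4 lowered, and without each macaque replicate there were 0 raised.

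Site variants were bound more weakly than flank variants by both proteins. The mean of the 9 site triplets exceeded that of the 8 flank triplets by 1.33 ± 0.20 kT in human, 3.79-fold, and by 0.271 ± 0.120 kT in macaque, 1.31-fold. The exact permutation test gave p = 0.333 (two-sided, n = 2 and 2), again the smallest possible. Without the triplet A978 to A980, an alternative chosen after seeing the data, the macaque value was 0.472 kT, and with medians it was 0.529 kT.

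Over the 1209 sequences other than the reference, which are not independent replicates, energies of the human reactions correlated at Pearson r = 0.995 and Spearman rho = 0.965. The macaque reactions gave r = 0.967 and rho = 0.919, and the 4 pairs between proteins r = 0.527 to 0.570 and rho = 0.660 to 0.764. The slope of human replicate 2 on replicate 1 was 1.245 ± 0.0037 (SE over sequences).

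The tables also hold 11 sequences named for HERVK9, a family of endogenous retroviruses, that the labels do not describe; they were tested after the data had been seen. HERVK9A2 differs from the reference by G979A, C989T and T992G, HERVK9A3 by G979A, A986G, C989T, T991C and T992A, and HERVK9B by these 5 and by A968G and A977G. Human ZNF626 bound HERVK9A2 and HERVK9A3 more tightly than the reference, at -1.10 ± 0.32 and -1.18 ± 0.11 kT, and HERVK9B lay at 0.027 ± 0.111 kT (adjusted p = 0.789, limma). Macaque ZNF626 bound them at -1.16 ± 0.13, -3.15 ± 0.11 and -2.76 ± 0.09 kT, the last a 15.7-fold tighter binding than the reference. HERVK9A3 and HERVK9B differed between the proteins by -1.96 and -2.78 kT (adjusted p = 2.44e-05 and 7.87e-06, limma), and HERVK9A2 by -0.066 kT (adjusted p = 0.739, limma). Relative to the controls, these differences were -0.226 kT for HERVK9A3 (adjusted p = 0.328, limma), -1.045 kT for HERVK9B and 1.67 kT for HERVK9A2, the last with tighter binding by human.

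**Figure D3:**
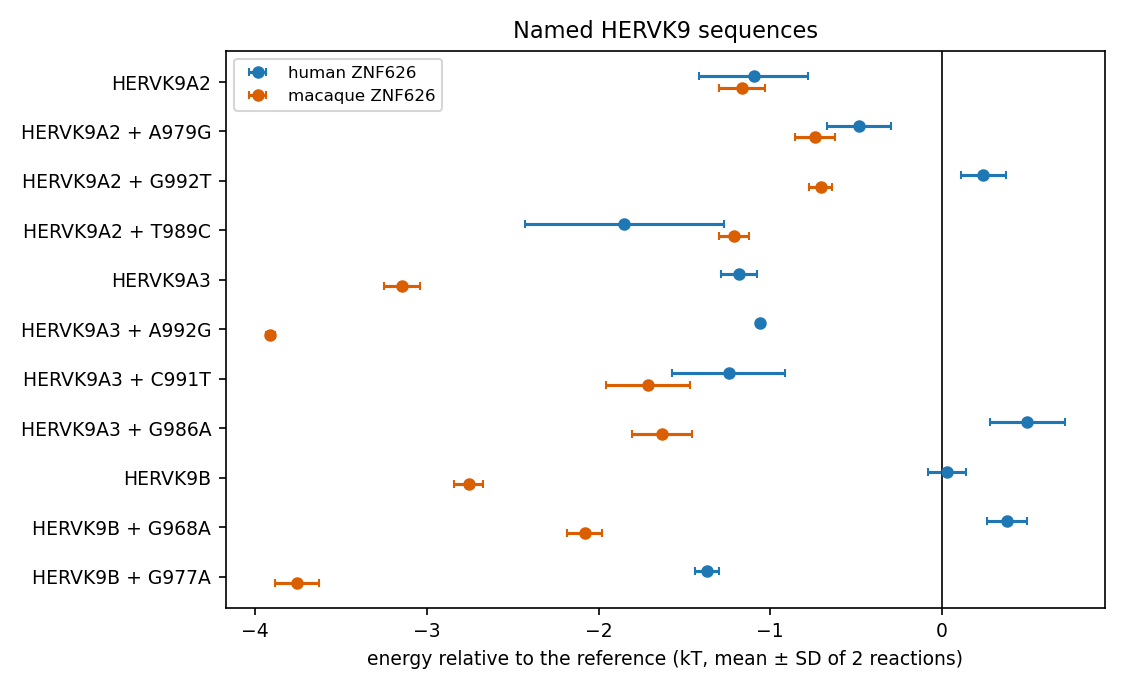
Energy of the 11 named HERVK9 sequences relative to the reference (x axis, kT, mean ± SD of 2 reactions) with human and macaque ZNF626. HERVK9B lies at 0.027 kT for human and -2.76 kT for macaque, and HERVK9A3 with A992G at -3.91 kT for macaque.

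The effect of 1 base in these backgrounds does not depend on the zero, and it differed between the proteins for 6 of 8 changes (limma). T989C in HERVK9A2 tightened human binding by -0.752 ± 0.262 kT, against -0.048 ± 0.049 kT in macaque (adjusted p of the difference 0.0294, limma). C991T in HERVK9A3 weakened macaque binding by 1.435 ± 0.138 kT, against -0.060 ± 0.222 kT in human (adjusted p = 0.00708, limma). G986A in HERVK9A3 weakened both, by 1.68 ± 0.32 kT in human and 1.52 ± 0.07 kT in macaque (adjusted p of the difference 0.445, limma), and for A979G in HERVK9A2 that p was 0.156. G977A in HERVK9B tightened both, by -1.395 ± 0.179 and -0.998 ± 0.042 kT.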

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

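Tests of the zero of the energy scale, of a mislabelled table, of a common factor, of protein amount, of flank substitutions and of reads counted as the reference were chosen after the results were seen. The background model of the human reactions was set before its result was seen. A first bound for A980T, a difference beyond 2 kT on every scale, was not met on the control scale (1.75 kT), and the criterion used below for the 16 variants was set after that.

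Each value in this part was picked out because the difference between the proteins itself passed a test (edgeR for variants, limma otherwise). For single variants relative to the reference, macaque minus human energies were -4.51 kT for G979A with A980T, -4.05 kT for G979T with A980T, -3.66 kT for G979C with A980T, -3.52 kT for A978C with G979A and A980T, and -3.48 kT for A980T. They were 0.953 kT for G979T, 0.891 kT for A978C with G979T, 0.890 kT for A978T with G979T, 0.845 kT for A978C with G979C and 0.787 kT for G993T with T995C.

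With the controls as zero the first 5 were -2.78, -2.31, -1.92, -1.78 and -1.74 kT and the others 2.69, 2.63, 2.63, 2.58 and 2.52 kT. By position the differences relative to the reference were -2.115 kT at A980, -1.28 at T991, -0.965 at C989, -0.807 at G990, -0.762 at A970, -0.756 at A988, -0.717 at C976, 0.695 at G979, -0.663 at A982 and -0.642 at A968. By triplet they were -1.315 kT at G990 to T992, -1.12 at A978 to A980, -0.870 at T987 to C989, -0.784 at C969 to G971 and -0.716 at G981 to A983. On the control zero, position A980 had -0.377 kT, T991 0.460, C989 0.773, G990 0.930, A970 0.976 and G979 2.43 kT, so that most of these signs turned. Among the HERVK9 sequences, macaque minus human energies relative to the reference were -0.948 kT for HERVK9A2 with G992T, -1.96 for HERVK9A3, -2.85 for HERVK9A3 with A992G, -2.13 for HERVK9A3 with G986A, -2.78 for HERVK9B, -2.46 for HERVK9B with G968A and -2.39 for HERVK9B with G977A. Relative to the controls they were 0.790, -0.226, -1.115, -0.388, -1.045, -0.718 and -0.648 kT in this order. The effects of single changes differed by -0.881 kT for G992T and 0.705 kT for T989C in HERVK9A2, by -0.889 kT for A992G and 1.496 kT for C991T in HERVK9A3, and by 0.328 kT for G968A and 0.397 kT for G977A in HERVK9B.

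The first pattern weighed was the tighter binding of variants with A980T by macaque. The zero of the scale changed its size but was not its whole cause, since the median of the 16 variants lay lower in both macaque reactions than in both human reactions on all 3 zeros, by -3.27 kT on the flank zero and -1.26 kT on the control zero. A swap of a single table between the proteins was argued against by the correlations, at most 0.570 between proteins and at least 0.967 within. An exchange of both tables of each protein would leave these correlations as they are, so they cannot decide on it. A common factor between the energies of the proteins was argued against by the residuals of the 16 variants from the line through the others, with a median of -9.09 residual SD and 16 of 16 beyond 2. This family was picked for its differences in these same data, so the residuals are not independent support. A different amount of active protein with equal base preferences would keep the order of variants, and this was argued against by a median of 11 other variants per A980T variant whose order was opposite by over 0.5 kT in every reaction, with at least 1 such variant for 12 of the 16. A difference between the proteins' own base preferences is a hypothesis that stays open, as does the preparation of each protein, which the labels do not give.

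The second pattern was that the reference was bound less than the variants of its flank in all 4 reactions. In the unbound libraries the reference had 40.4 to 44.3 times the reads of a median flank variant. The 18 triplets, each of which can yield the reference once, would give 18 times, and the source of the other reads was not tested. Strengthening by flank substitutions with effects that add was argued against, since the median energy of triple flank variants was at most 0.983 times that of single ones in the human reactions. Strengthening that does not grow with the number of substitutions was not tested. A mixture of reference reads with reads of other variants cannot have a bound/unbound ratio below both of its parts. If the reference itself were bound at least as tightly as its flank variants, the mixture could not lie below these and the donors alike. In macaque the reference was at 0.816 and 0.824 times the flank ratio. It was at most at 0.924 times the ratio of all variants or of single-substitution variants, with or without those that carry A980T. This argued against such reads at equal rates as the whole cause. In human the reference was at 0.668 and 0.601 times the flank ratio and at 0.872 and 0.768 times that of the single-substitution variants. This argued against reads of these as the whole cause. For reads of all variants at equal rates the values were 1.075 and 0.994 in the human reactions, and 1.09 and 1.02 without A980T, so this stays open there, as do unequal rates in both proteins, and no biological explanation was tested.

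The third pattern was the wider energy range of human replicate 2, with a slope of 1.245 on replicate 1, and macaque replicate 2 shared it with a slope of 1.137. A constant background of unbound DNA in the bound fraction of replicate 1 was argued against, because its model had a residual SD on the log scale 1.30 times that of a power law (95% bootstrap interval over sequences 1.24 to 1.37), although its intercept of 0.0815 lay above 0. No biological explanation was tested, and the cause stays open.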

How the results depend on the processing

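In place of the scale on the controls, scales that do not refer to them gave in human 591 more and 513 less with TMM, 586 and 513 with DESeq2 and 76 and 561 on the flank variants, and in macaque 199 and 278, 141 and 423, and 119 and 349, and on the control scale macaque had 287 less under no replicate block and 0 less with its own libraries. Against the reference, the control scale gave 954 and 0 in human and 97 and 182 in macaque, and macaque had 393 more under no replicate block and 143 more and 7 less with its own libraries. The difference between proteins had 514 less with TMM, 523 with DESeq2, 15 on the flank scale, 459 under no replicate block, and 14 more and 1070 less on the control scale. Of alternatives chosen after seeing the data, the crossed replicate block gave 151 more and 367 less in macaque against the controls, and leaving out the triplet A978 to A980 gave 0.472 kT for site minus flank in macaque, r = 0.939 between macaque reactions and a mean r of 0.6139 between proteins. That mean was 0.6487 for single substitutions and 0.5801 without controls. On the flank zero, lowered positions were 4 in human and 7 in macaque with 1 raised in the difference, and lowered triplets were 0 in human and 2 in macaque with 0 raised in the difference. On the reference zero, macaque had 16 lowered positions by additive regression and 3 lowered triplets by medians. Medians gave 1.63 kT and 0.529 kT for site minus flank, and controls minus flank was 2.19 kT in human and 0.181 kT in macaque. On the control scale the human energies of C969T with A970C and G971C, A970C with G971C, A970T with G971C, T987C with A988G and C989G, and A970G with G971T changed sign to -0.168, -0.169, -0.207, -0.207 and -0.211 kT, none past the test (adjusted p from 0.310 to 0.414, edgeR). Additive regression gave -0.005 kT for the difference at G979. The zero on the controls, chosen after seeing the data, gave 52 raised and 0 lowered positions and 17 raised and 0 lowered triplets for macaque minus human, and turned the sign at T991 (0.460 kT), C989 (0.773), G990 (0.930), A970 (0.976), A988 (0.982), C976 (1.021), A982 (1.075) and A968 (1.096), and in the triplets that start at G990 (0.423), A978 (0.620), T987 (0.868), C969 (0.954) and G981 (1.022).

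With 1 reaction left out, counts against the controls ranged from 700 to 1112 more in human and from 53 to 89 more and 0 to 390 less in macaque. Against the reference they ranged from 559 to 576 more and 501 to 509 less in human, 105 to 145 and 2 to 300 in macaque, and 164 to 527 and 8 to 313 for the difference. Raised and lowered positions ranged over 20 to 20 and 32 to 33 in human, 4 to 16 and 8 to 36 in macaque, and 1 to 25 and 15 to 19 for the difference, and triplets over 7 to 9 and 8 to 9, 0 to 6 and 1 to 10, and 0 to 8 and 4 to 10. Site minus flank ranged from 1.194 to 1.470 kT in human and 0.186 to 0.356 kT in macaque, and control minus reference from 1.576 to 1.877 and -0.129 to 0.107 kT.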

Other observations

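The additivity test was chosen after part of the values had been seen, and the families of bases below were picked after the values were seen. The floor test was set before its result was seen.

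The preference of macaque in the triplet A978 to A980 depended on the base at its last position. The 16 variants with A980T had a median energy of -3.46 ± 0.09 kT relative to the flank in macaque and -0.184 ± 0.092 kT in human, and the 16 with A980C -1.225 ± 0.138 and 0.653 ± 0.073 kT. Relative to the controls they were -3.64 in macaque and -2.37 kT in human for A980T, with 7 of 16 bound more by macaque, and -1.41 and -1.535 kT for A980C, with 0 more and 2 less. These 16 A980T variants made up 21.0% and 20.8% of the bound macaque reads and 1.07% and 1.01% of the unbound ones, against 2.74% and 3.45% of the bound human reads. In triplet G990 to T992, the 16 variants with T991C lay at -0.805 ± 0.100 kT relative to the controls in macaque and -0.376 ± 0.012 kT in human, and 12 and 5 of them were bound more than the controls. The 16 variants with A965T, outside the stated site, lay at -0.523 ± 0.113 kT relative to the flank in macaque and -0.210 ± 0.078 kT in human, with 14 bound more than the controls by macaque and 16 by human. With the controls as zero, human bound these more tightly, at -2.40 against -0.705 kT. Those with A968G lay at -0.511 ± 0.073 and 0.299 ± 0.046 kT relative to the flank, and at -0.692 and -1.89 kT relative to the controls.

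Single substitutions that both proteins bound more tightly than the flank variants included A986G, C975G and A978C, at -1.06 ± 0.22, -0.979 ± 0.288 and -0.787 ± 0.253 kT in human and -1.24 ± 0.16, -1.10 ± 0.11 and -0.927 ± 0.066 kT in macaque. Taken against the flank level, the reference base was the best base at 21 of 29 positions of the stated site in human and 15 in macaque, and the best base was shared by both proteins at 21.

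A hypothesis that effects of single substitutions add across the site was tested on the HERVK9 sequences. With the zero on the flank variants, the data did not bear it out. On that zero the sum lay within 0.5 kT of the measured energy for 5 of 11 sequences in human and 5 in macaque. The 6 others in each protein were bound more tightly than the sum on the flank zero, by up to -2.20 kT for HERVK9B in human and -1.07 kT for HERVK9A3 with A992G in macaque. These deviations depend on the zero. The flank variants lay at -0.462 ± 0.080 kT in human and -0.193 ± 0.015 kT in macaque relative to the reference. A change of zero enters a sum once per substitution. On the reference zero the deviations of these sequences become smaller or turn sign, while the same shift can carry other sequences away from their sums. Additivity was not tested there, so the result on the flank zero does not decide on the hypothesis. On the flank zero, all 5 sequences that carry T991C with A986G exceeded 0.5 kT in both proteins, as did HERVK9A3 with G986A. In macaque, T991C alone had -0.405 ± 0.111 kT relative to the flank, while its reversal in HERVK9A3 cost 1.435 ± 0.138 kT.

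A floor at the level of the controls, taken here as non-specific binding, may explain part of the shortfall in human. The sums and the control level here are on the flank zero, and the floor was not tested on the reference zero. Of 270 double variants outside the flank, 105 had a summed energy above the controls and measured -0.396 kT from the controls in the median, that is -1.27 kT from the sum. The 128 whose sum lay over 0.5 kT below the controls deviated from it by 0.310 kT in the median of absolute values and by 0.185 kT with signs kept. A floor alone explains none of the 6 HERVK9 sequences that deviated in human on that zero. HERVK9A3, its forms with A992G and G986A and HERVK9B with G977A had sums of 1.06, 0.275, 2.12 and 1.09 kT, below the control level of 2.19 kT, and HERVK9B and HERVK9B with G968A had sums above it but measured 0.490 and 0.838 kT.

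The variant A957T with T959C had the largest gap between the macaque reactions, at -2.07 and 0.778 kT, and in human, where HERVK9A2 with T989C had the largest at 0.817 kT, it lay at -0.626 and 0.109 kT. The replicate 1 and 2 deviations of energies correlated at 0.443 between the proteins over sequences, and those of the bound libraries at 0.546, although the labels name nothing shared by reactions of the same number. With a replicate block across proteins, 25 positions were raised and 20 lowered in macaque against human, where 22 and 18 were called without it.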
